A study of Mus musculus with 6 samples.

How the data were processed

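Bulk RNA sequencing of mouse liver was analysed from 6 libraries, 3 of the genotype labelled Control and 3 of the genotype labelled Cyr61 KO. Per the labels, the mice were male, 24 weeks old, of a strain carrying floxed Cyr61 alleles, and had received a NASH (non-alcoholic steatohepatitis) diet for 12 weeks. The livers were flash frozen, and the libraries were made with a directional kit. The labels give the same strain for both groups and do not say by what means or in which cells the gene was removed. They also do not state that each library came from a separate mouse, so p-values measure the spread between these libraries. Groups and replicate numbers were taken from the labels.

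The values used were read counts per gene, deposited by the authors as 1 table per library with 24411 gene symbols. Per the submitters' processing notes, Trimmomatic 0.38 and STAR 2.6.1a were used, and the builds hg38 and mm10 were listed. The annotation release and the mapping settings are not given in the sources used here. Each deposited table holds unstranded counts and counts for either strand. The strand that fits the directional kit held 21032878 to 40377742 counts per library, and the opposite strand 0.928% to 1.35% of the stranded counts. A table of the whole series held the unstranded counts in 100% of its rows and was not tested separately. Reads that were unmapped, mapped to several positions, fell outside genes or fell in several genes stayed out of library sizes and tests. Reads outside genes made up 4.27% to 7.14% of the reads in 5 libraries and 25.7% in control replicate 2.

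Genes were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test, two-sided, after filterByExpr with a minimum count of 10 and a minimum total count of 15, TMM normalisation and a group term only. This left 13563 genes. Benjamini-Hochberg adjusted p below 0.05 was called. Expression is given as TMM-normalised CPM, counts scaled to a common library size by edgeR's cpm function, and fold changes as log2 of Cyr61 KO over control with a standard error computed as the absolute log2 fold change over the square root of F. An exact permutation test of 3 libraries against 3 cannot give a two-sided p below 0.1, so none was used. The 40 gene lists and the rule for named genes were fixed before the data were examined. The lists were tested with camera of limma 3.58.1 on voom values at a preset inter-gene correlation of 0.01, for the 37 lists with at least 4 tested members. Camera with an estimated correlation and fry were alternatives. Where no other test is named, a list that passed did so by camera with the preset correlation. The lists hold 759 distinct genes, of which 739 were in the tables. The mitochondrially encoded list had 0 tested members, the pancreas and gut list 2 and the erythroid list 3.

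The rule for named genes takes Cyr61, the genes of the series title with 5 fibrosis genes, the 10 higher and 10 lower called genes with the largest change at a mean CPM of at least 1 and no overlap between the groups, and up to 4 members of each list by p. Lists with no call give at most 2 members by CPM. Unnamed gene models and pseudogenes were left out of the ranking. Some genes that the rule takes are not reported here. Positions come from GENCODE M21 on GRCm38, the assembly of mm10, which placed 160 of the 161 named genes through current or older symbols.

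The tests were checked on simulated counts for Cyr61 KO against control, 5 simulations of 13563 genes with 200 changed. edgeR recovered 0.4% of genes changed 1.5-fold, 12.4% at 2-fold, 84.4% at 4-fold and 95.6% at 8-fold, with a mean of 5.4 false calls. DESeq2 1.42.0 recovered 5.2%, 35.2%, 94.8% and 98.8% at the same folds, with a mean of 34 false calls. In simulated lists of 20 genes raised 1.5-fold, camera called 25 of 25 with the preset correlation and 24 of 25 with an estimated one. It called 0 of 100 unchanged lists in either mode. The simulated genes varied independently of each other, whereas the correlations estimated within the tested lists ran from -0.04 to 0.87. The simulation therefore cannot show that the preset of 0.01 holds for the real lists.

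The alternatives were DESeq2, limma voom with quality weights, DESeq2's size factors, library totals without further scaling, no low-count filter, a CPM of at least 1 in 3 libraries, unstranded counts, the replicate number as a block, a test against a minimum fold of 1.5 and leaving out each library in turn. Further gene lists, unweighted voom and 4 settings that leave out control replicate 2 were added after the data were seen. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom was 57.8 or more in every pair.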

Results

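Gene expression was measured by bulk RNA sequencing in livers of male mice after 12 weeks of a NASH diet, in 3 Cyr61 KO and 3 control libraries. Cyr61 (Ccn1) encodes a secreted matricellular protein, and the series title places it upstream of SYK, NF-kB and PDGF signalling in monocyte-derived macrophages during liver fibrosis. The comparison therefore asks which liver transcripts differ without Cyr61. Control replicates 1, 2 and 3 held 34827903, 21032878 and 34826395 gene counts, while Cyr61 KO replicates 1, 2 and 3 held 40377742, 31133292 and 35384607. Control replicate 2 stood apart, with 50.9% of its reads counted in genes against 82.8% to 87.6% in the other libraries. It also had Malat1, a nuclear long RNA, at 3738 CPM against 56.5 to 128 CPM, Dmbt1, a mucosal epithelial gene, at 1151 CPM against at most 0.449 CPM, and Alb, the hepatocyte albumin gene, at 23799 CPM against 66177 to 90103 CPM. These 3 genes were chosen after their values were seen.

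**Figure D1:**
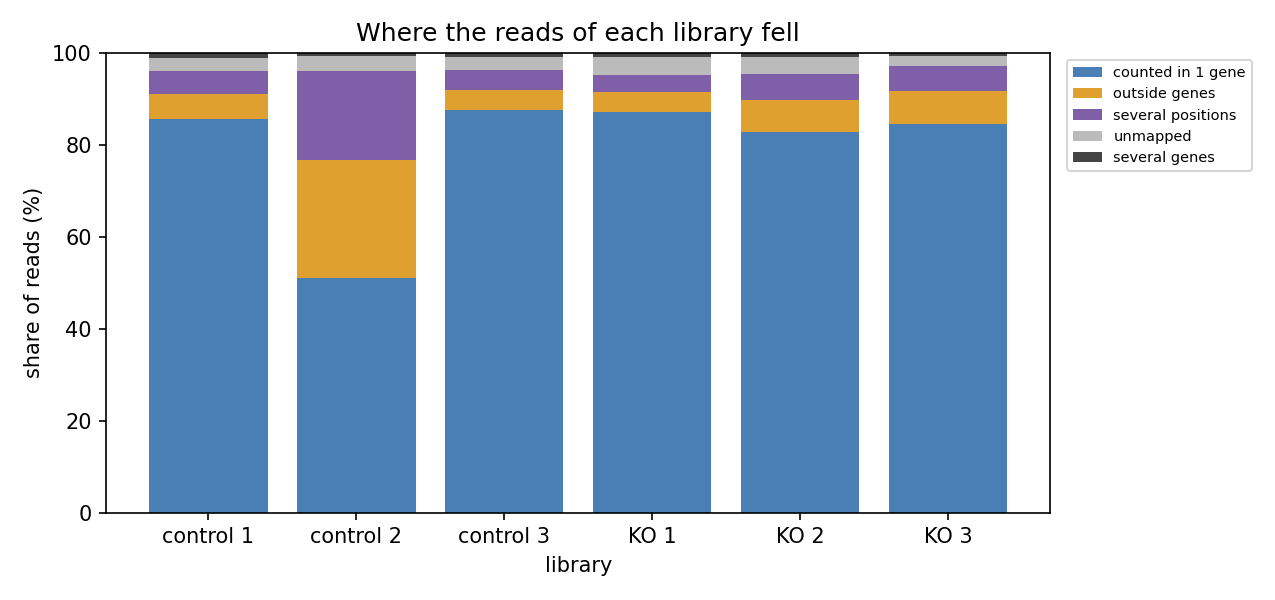
Share of reads (%) in each library that were counted in 1 gene, fell outside genes, mapped to several positions, stayed unmapped or fell in several genes, for 3 control and 3 KO libraries. In control 2, 25.7% of the reads fell outside genes and 19.4% mapped to several positions.

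Cyr61 was lower in every Cyr61 KO library than in every control library. The gene lies on chromosome 3 from 145646976 to 145649981 on the minus strand. It was measured at 15.6, 32.4 and 27.8 CPM in control replicates 1, 2 and 3 and at 3.77, 2.66 and 3.14 CPM in the knockouts. The means were 25.2 ± 8.71 CPM (SD, n = 3) and 3.19 ± 0.558 CPM (SD, n = 3), so 12.6% of the control level remained. The log2 fold change was -2.98 with a standard error of 0.32 (edgeR adjusted p = 0.0103). Without Cyr61 KO replicate 1 it was -3.10 with an adjusted p of 0.0615.

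Of the 13563 genes tested, 145 were higher and 322 lower in Cyr61 KO livers by edgeR, 467 in all. The groups did not overlap in any of the 467. They did not overlap in 35.2% of all tested genes, where chance gives 10% on average over the ways to split the libraries. Genes that vary together can move this share far from 10% in any given split, so the difference is not a test. The largest increases included Hsd3b5, a male-biased steroid dehydrogenase gene, at a log2 fold change of 5.28 ± 0.96 (SE), the organic anion transporter gene Slco1a1 at 4.23 ± 0.47, and Cyp4a14, Cyp2c54 and Cyp2c37 at 4.11, 3.90 and 3.87. Plcxd1, Cd163, Rgs16, Acss3 and Slc15a5 followed, from 3.83 down to 2.97. The largest decreases were those of Lrtm2 at -6.09 ± 0.64 and Wfdc15b at -5.11 ± 0.43, followed by Prtn3, S100a4, Klra17, Ubd, Saa2, Bcl2a1d, Tff3 and Lcn2, from -4.73 to -4.13. Some of these changes depended on the libraries kept. Hsd3b5 was at 78.4 and 106 CPM in Cyr61 KO replicates 1 and 2 but at 6.81 CPM in replicate 3. S100a4 and Klra17 were at 18.3 and 5.37 CPM in control replicate 2, and at -2.88 and -3.52 on the log2 scale without it. Prtn3 and Saa2 were at 11.7 and 1030 CPM in control replicate 3, and at -2.77 and -2.92 without it. Each of the 4 still passed without the control named. Without control replicate 2 Hsd3b5, Slc15a5, Prtn3 and Tff3 did not pass (edgeR adjusted p = 0.0792, 0.0549, 0.0566 and 0.0605). Hsd3b5, Cd163, Slc15a5 and Tff3 did not pass without control replicate 1, nor Prtn3 and Tff3 without Cyr61 KO replicate 3. Of the genes named in this paragraph, Cyp4a14, Cyp2c37, Rgs16 and Wfdc15b alone still passed without Cyr61 KO replicate 1. Genes of the Cyp2c, Cyp4a, Saa and Bcl2a1 families have close copies, and their counts are uncertain to that extent. The count of called genes rested on single libraries: it was 174, 293 and 878 without control replicates 1, 2 and 3, and 7, 24 and 773 without Cyr61 KO replicates 1, 2 and 3. Without Cyr61 KO replicate 1 edgeR called 1 gene each in the fatty acid oxidation and stellate lists and 0 in every other list. With library totals as the only scaling, 27 genes were higher and 23 lower, so that 54% of the calls were increases against 31.0% with TMM, and the median log2 fold change of all genes moved from -0.03 to -0.30.

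**Figure D2:**
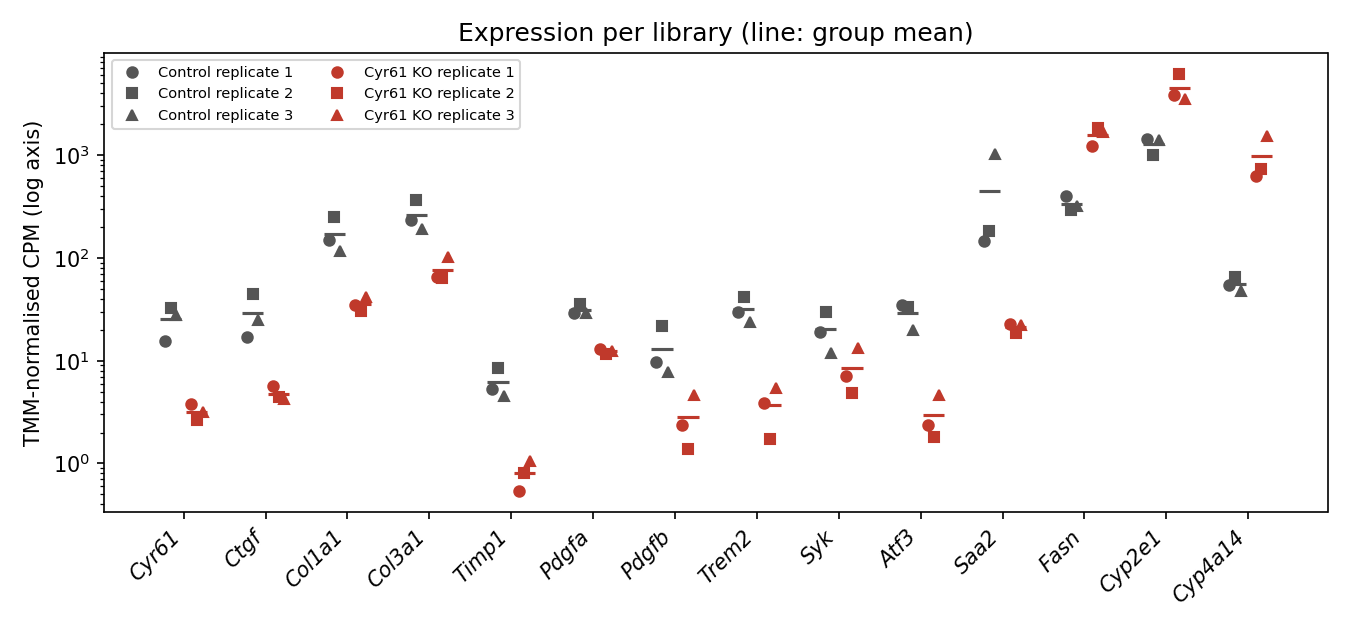
TMM-normalised CPM on a log axis for 14 genes in each library, with 3 control and 3 Cyr61 KO libraries and lines at the group means. Cyr61 lies between 15.6 and 32.4 CPM in the controls and between 2.66 and 3.77 CPM in the knockouts, while the groups overlap for Syk.

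Genes of fibrosis and extracellular matrix were lower in the knockouts. Of 40 members, 15 were called lower and 0 higher, or 32 lower when adjusted over the list alone, with a median log2 fold change of -1.39 (camera adjusted p = 8.6e-15, and adjusted p = 0.394 with an estimated correlation). Col1a1, a chain of type I collagen on chromosome 11 from 94936224 to 94953042, fell from 173.0 ± 70.6 to 35.8 ± 5.73 CPM (SD, n = 3), a log2 fold change of -2.27 (edgeR adjusted p = 0.0184). Col1a2 fell by 1.67, Col3a1 by 1.78, Col5a2 by 1.76 and Lum by 2.03 on the log2 scale, and Timp1, an inhibitor of matrix metalloproteinases, fell by 2.93. Acta2, the smooth muscle actin of activated stellate cells, had a log2 fold change of -2.97 that did not pass (edgeR adjusted p = 0.0552). It was at 31.3 CPM in control replicate 2 against 4.44 and 6.19 CPM in the other controls, and at -1.55 without that library (edgeR adjusted p = 0.0558). Of the 4 tested CCN genes, 3 were called lower and 3 when adjusted over the list alone (camera adjusted p = 7.8e-04, and adjusted p = 0.394 with an estimated correlation). The called genes were Cyr61, Ctgf at -2.59 and Wisp2 at -3.51, while Wisp1 was at -0.63. Cyr61 is the gene removed, so its decrease follows from the design and adds to the count and the camera result. Without it the list would fall below the 4 tested members needed for a test. Among PDGF ligands and receptors 1 of 6 was called lower, or 4 when adjusted over the list alone (camera adjusted p = 9.9e-04, and adjusted p = 0.394 with an estimated correlation). Pdgfa fell by 1.33 on the log2 scale (edgeR adjusted p = 0.0184), Pdgfb at -2.20 missed the threshold (0.0569), and Pdgfrb, Pdgfra, Pdgfd and Pdgfc at -0.84, -0.87, -1.68 and -0.29 did not pass. Control replicate 2 had the highest Col1a1 value, 252 CPM, and without it 9 matrix genes were called lower at a median of -1.10. Without control replicate 1, 8 were called by edgeR, and without Cyr61 KO replicate 1 or 2, 0 and 0, where the list still passed at medians of -1.21 and -1.36 (camera adjusted p = 6.0e-11 and 1.5e-16). Of the CCN genes 0 and 1 were then called, and of the PDGF genes 0 and 0, while both lists still passed by camera at the preset correlation. With library totals as the only scaling, edgeR called 0 matrix, 1 CCN and 0 PDGF genes lower, at a matrix median of -1.73. The 3 lists still passed by camera at the preset correlation in that setting.

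Markers of monocyte-derived macrophages were lower as well. Of 21 members, 9 were called lower and 0 higher, or 18 lower when adjusted over the list alone, with a median of -2.52 (camera adjusted p = 3.0e-10, and adjusted p = 0.394 with an estimated correlation). Trem2, a lipid-sensing receptor of disease-associated macrophages, fell by 3.09 on the log2 scale, Ms4a7 by 2.99, Lgals3 by 2.61 and Plac8 by 2.44. Among SYK and its adaptor receptors 2 of 20 were called lower, or 17 when adjusted over the list alone (median -1.59, camera adjusted p = 7.7e-08, and adjusted p = 0.394 with an estimated correlation). The called members were Clec7a at -2.57 and Tyrobp at -2.12. Syk itself was at -1.26 ± 0.43 and did not pass (edgeR adjusted p = 0.112). Of 28 NF-kB target genes 6 were called lower, or 22 when adjusted over the list alone (median -1.83, camera adjusted p = 4.8e-10, and adjusted p = 0.394 with an estimated correlation), among them Bcl2a1b at -3.33, Lcn2 at -4.13 and Vcam1 at -1.70. The subunit genes Nfkb1 and Rela were at -0.21 and -0.03 and did not pass. Control replicate 2 had the highest Trem2 and Syk values, 41.4 and 29.6 CPM. Without it 4 macrophage, 0 SYK and 3 NF-kB genes were called lower by edgeR, at medians of -1.83, -1.02 and -1.42. Of the SYK genes 10 then had an unadjusted p under 0.05 and DESeq2 called 6. Without Cyr61 KO replicate 1 edgeR called 0 genes in each of the 3 lists, at medians of -2.36, -1.43 and -1.58, and without replicate 2 it called 2, 0 and 0, at -2.35, -1.27 and -1.64. Without control replicate 3 it called 15, 8 and 18, and without Cyr61 KO replicate 3 it called 15, 13 and 13. With library totals as the only scaling it called 0, 0 and 0, at medians of -2.93, -1.90 and -2.12. The 3 lists still passed by camera at the preset correlation in that setting.

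The other immune cell lists were also lower. Called lower were 2 of 9 neutrophil markers, including S100a9 at -3.90, 4 of 14 dendritic cell markers, including H2-Eb1 at -2.84 and Cd74 at -2.37, 1 of 14 T and NK cell markers, Cd8b1 at -3.92, and 1 of 9 B and plasma cell markers, Jchain at -3.28. Adjusted over the list alone, the counts were 9, 11, 13 and 3. The camera adjusted p were 1.3e-04, 5.0e-06, 1.4e-04 and 0.0124, and the adjusted p were 0.394, 0.394, 0.453 and 0.427 with an estimated correlation. Without Cyr61 KO replicate 1 edgeR called 0 genes in each of these 4 lists, and likewise without replicate 2. Without control replicate 2 it called 2, 4, 0 and 1. The counts were 6, 3, 1 and 1 without control replicate 1, and 4, 9, 11 and 2 without control replicate 3. They were 3, 5, 0 and 1 without Cyr61 KO replicate 3. All 4 lists still passed by camera at the preset correlation in these settings. Their estimated correlations in the full comparison were 0.66, 0.77, 0.87 and 0.38. With an estimated correlation and without control replicate 2, their camera adjusted p were 0.334, 0.344, 0.334 and 0.334. Control replicate 2 had the highest values of S100a9, Cd3e and Jchain among the controls, at 25.3, 9.74 and 36.4 CPM, and without it the T and NK median moved from -2.75 to -1.18 and the B and plasma cell median from -1.74 to -0.58. Cd8b1 was then at -2.48 and no longer passed (edgeR adjusted p = 0.0542). With library totals edgeR called 0 genes in each of the 4 lists, and the B and plasma cell call was lost (camera adjusted p = 0.0534). Of the cholangiocyte markers 0 were called without control replicate 2, Cyr61 KO replicate 1 or Cyr61 KO replicate 2, but 11 were called lower without control replicate 3. Cholangiocyte markers were lower at a median of -2.56, or -1.12 without control replicate 2, with 2 of 18 called, Krt23 at -2.57 and St14 at -2.39, or 12 lower and 1 higher when adjusted over the list alone (camera adjusted p = 8.7e-05, and adjusted p = 0.436 with an estimated correlation). Of 16 stellate cell markers 4 were called lower, or 5 when adjusted over the list alone, including Cygb at -1.51 (camera adjusted p = 0.00418, and adjusted p = 0.462 with an estimated correlation). Endothelial markers were higher, with Kdr at 1.16 and Clec4g at 0.90 called among 18, or 3 when adjusted over the list alone (median 0.13, camera adjusted p = 0.0477, and adjusted p = 0.655 with an estimated correlation). Without control replicate 2 the endothelial median was 0.58 (camera adjusted p = 2.1e-05). The endothelial call was lost without control replicate 1, control replicate 3 or Cyr61 KO replicate 3, at medians of -0.04, -0.04 and -0.04 (camera adjusted p = 0.388, 0.285 and 0.200). The stellate call was lost without Cyr61 KO replicate 1 (0.159). The endothelial call was also lost with a CPM of at least 1 in 3 libraries (0.0826), with unstranded counts (0.0504) and with the replicate block (0.0615, median 0.25). With library totals the endothelial median was -0.25, where that of all genes was -0.30. Of 16 Kupffer cell markers 1 was called higher and 2 lower, or 3 and 4 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.273) except without Cyr61 KO replicate 3 (0.00608, median -0.95). Cd163, a scavenger receptor, rose by 3.48 on the log2 scale, and Hmox1 and C1qa fell by 1.66 and 1.55.

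**Figure D3:**
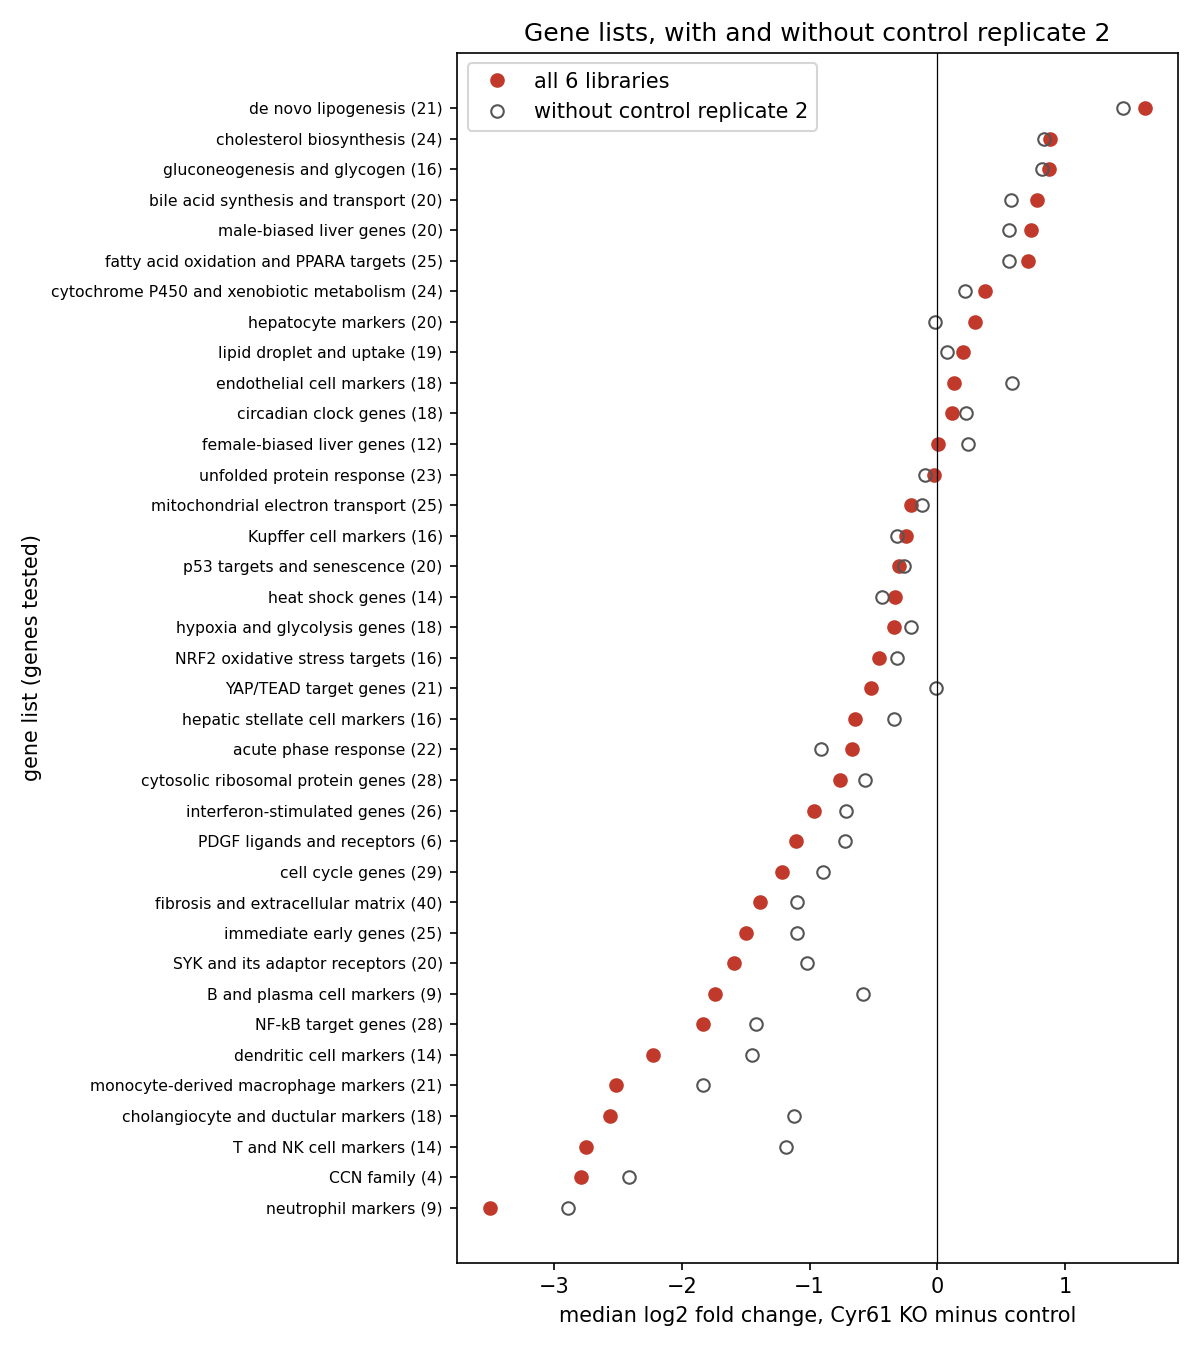
Median log2 fold change (x axis, Cyr61 KO minus control) of the tested genes in each of 37 lists, with the number of genes tested in brackets. Filled points use all 6 libraries and open points leave out control replicate 2, which moves the T and NK cell median from -2.75 to -1.18 and the matrix median from -1.39 to -1.10.

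Of 25 immediate early genes 8 were called lower, or 16 when adjusted over the list alone, among them Atf3 at -3.31, Jun at -1.53, Egr1 at -2.66 and Egr2 at -2.74 (camera adjusted p = 3.2e-08, and adjusted p = 0.394 with an estimated correlation). Of 22 acute phase genes 5 were called lower, or 7 when adjusted over the list alone, including Saa3 at -2.54 and Orm2 at -2.99 (camera adjusted p = 0.0044, and adjusted p = 0.468 with an estimated correlation). Interferon-stimulated genes had 8 of 26 called lower, or 11 when adjusted over the list alone, including Cxcl9 at -1.41 and Irf7 at -1.22 (camera adjusted p = 8.8e-07, and adjusted p = 0.394 with an estimated correlation). Of the heat shock genes, Hspa1b and Hspa1a fell by 2.13 and 3.22 on the log2 scale, 2 of 14, or 4 when adjusted over the list alone (camera adjusted p = 0.0124, and adjusted p = 0.394 with an estimated correlation). Of 20 p53 targets 1 was called lower, or 2 when adjusted over the list alone (camera adjusted p = 0.0124, and adjusted p = 0.461 with an estimated correlation). Of 16 NRF2 targets 1 was called lower, Hmox1, or 3 when adjusted over the list alone (camera adjusted p = 0.0475, and adjusted p = 0.572 with an estimated correlation). Cell cycle genes had 0 of 29 called by edgeR, also 0 when adjusted over the list alone. Of these 12 had an unadjusted p under 0.05, DESeq2 called 6 lower, and edgeR called 19 without Cyr61 KO replicate 3, at a median of -2.63. The list mean was 2.49 log2 CPM in Cyr61 KO replicate 3, within the controls at 2.22 to 3.28, and 0.70 and 0.44 in Cyr61 KO replicates 1 and 2. Mcm5 was at -1.57 (list median -1.21, camera adjusted p = 4.3e-08, and adjusted p = 0.394 with an estimated correlation). Ribosomal protein genes, listed as a measure of RNA quality, had 1 of 28 called lower, Rps24 at -1.66, or 4 when adjusted over the list alone (camera adjusted p = 3.2e-08, and adjusted p = 0.394 with an estimated correlation). All 28 had a negative log2 fold change, at a median of -0.76. Of 23 unfolded protein response genes 5 were called lower, including Ddit3 at -2.71, Asns at -2.19 and Fgf21 at -2.76, or 6 lower and 5 higher when adjusted over the list alone, while the list did not pass (camera adjusted p = 0.559). Calls of lists were lost without control replicate 3 for acute phase and heat shock genes (camera adjusted p = 0.0809 and 0.0809), without Cyr61 KO replicate 3 for heat shock genes (0.0634) and without Cyr61 KO replicate 2 for p53 targets (0.0712). The NRF2 call was lost without control replicates 1 and 3 (0.222 and 0.0580) and Cyr61 KO replicates 1 and 2 (0.215 and 0.0620), with library totals (0.0635) and with a CPM of at least 1 in 3 libraries (0.0597). Without control replicate 2 the called immediate early and interferon-stimulated genes numbered 4 and 3, and without control replicate 1, 3 and 1. Without Cyr61 KO replicate 1 they numbered 0 and 0, and without replicate 2, 1 and 0, while both lists still passed by camera at the preset correlation. Acute phase and heat shock genes had 0 called without either of these knockouts.

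Of 21 genes of de novo lipogenesis 9 were called higher and 0 lower, or 15 higher and 1 lower when adjusted over the list alone (median 1.62, camera adjusted p = 1.5e-10, and adjusted p = 0.394 with an estimated correlation). Fasn, the fatty acid synthase gene, rose from 338 ± 53.2 to 1583 ± 320.3 CPM (SD, n = 3), a log2 fold change of 2.23 (edgeR adjusted p = 0.0184). Me1 rose by 2.36, Acacb by 2.51 and Acss2 by 1.92 on the log2 scale. Cholesterol biosynthesis had 5 of 24 called higher, or 16 when adjusted over the list alone, including Hmgcs1 at 1.16 and Stard4 at 1.83 (camera adjusted p = 3.0e-10, and adjusted p = 0.394 with an estimated correlation). Of 25 genes of fatty acid oxidation and PPARA targets 3 were called higher and 1 lower, or 9 and 1 when adjusted over the list alone, with Cyp4a10 at 2.87, Acot1 at 1.65 and Fgf21 at -2.76 (camera adjusted p = 3.0e-07, and adjusted p = 0.394 with an estimated correlation). Bile acid synthesis and transport had 3 of 20 called higher, or 6 higher and 1 lower when adjusted over the list alone, including Cyp8b1 at 2.68 and Slc10a1 at 2.27 (camera adjusted p = 6.7e-05, and adjusted p = 0.394 with an estimated correlation). In gluconeogenesis and glycogen 2 of 16 were called higher, Ppp1r3b at 2.02 and Ppp1r3c at 1.90, or 9 higher and 2 lower when adjusted over the list alone (camera adjusted p = 1.7e-04, and adjusted p = 0.394 with an estimated correlation). Cytochrome P450 and xenobiotic genes had 6 of 24 called higher, or 8 higher and 3 lower when adjusted over the list alone, including Cyp2c50 at 2.94, Nr1i3 at 1.61 and Cyp1a2 at 1.57 (camera adjusted p = 0.0143, and adjusted p = 0.453 with an estimated correlation). Of 20 hepatocyte markers 1 was called higher, Cyp2e1 at 1.83, and 1 when adjusted over the list alone (camera adjusted p = 0.0317, and adjusted p = 0.591 with an estimated correlation), and the hepatocyte and P450 lists did not pass without control replicate 2 (camera adjusted p = 0.386 and 0.0645). The hepatocyte call was also lost without Cyr61 KO replicates 1 and 2 (0.140 and 0.0554), and the P450 call without replicate 3 (0.0793). Lipogenic genes called higher numbered 3 without control replicate 1, 12 without control replicate 2, and 0 and 0 without Cyr61 KO replicates 1 and 2, where the list medians were 1.53 and 1.48. For cholesterol biosynthesis the number was 0 without control replicate 1, 4 without control replicate 2, and 0 and 0 without Cyr61 KO replicates 1 and 2. That list still passed by camera at the preset correlation each time. Without Cyr61 KO replicate 1 edgeR called 0 bile acid, 0 gluconeogenesis and 0 P450 genes, and 1 gene of fatty acid oxidation.

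Of 20 male-biased liver genes 3 were called higher, Slco1a1, Elovl3 at 2.84 and Hsd3b5, or 8 higher and 2 lower when adjusted over the list alone (camera adjusted p = 1.7e-04, and adjusted p = 0.394 with an estimated correlation). Without control replicate 2 edgeR called 2 male-biased genes higher and 1 lower, and without Cyr61 KO replicates 1 and 2 it called 0 and 1. The list still passed by camera at the preset correlation in these settings. Of 18 clock genes 2 were called higher, including Npas2 at 1.74, and 1 lower, Per1 at -1.78, or 7 higher and 2 lower when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.226). The lists of YAP/TEAD targets, hypoxia and glycolysis, mitochondrial electron transport, female-biased genes and lipid droplets did not pass either, at camera adjusted p of 0.109, 0.0945, 0.345, 0.605 and 0.846. The hypoxia list passed with fry (adjusted p = 0.0394). Called lower were 3 of 21 YAP/TEAD targets, Cyr61, Ctgf and Ccdc80 at -1.44, 2 of 18 hypoxia genes, P4ha1 at -1.19 and Pkm at -1.49, and 1 of 19 lipid droplet genes, Lpl at -1.86. The YAP/TEAD count includes Cyr61, the gene removed. Adjusted over the list alone, 2 YAP/TEAD targets were higher and 4 lower, 2 hypoxia and 2 lipid droplet genes were lower, and 1 of 12 female-biased genes was higher and 1 lower. Of 25 electron transport genes edgeR called 0, also 0 when adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 1 higher and 1 lower by DESeq2. The YAP/TEAD list passed without control replicate 3 and without Cyr61 KO replicate 3 (camera adjusted p = 0.0362 and 0.0228), and with the replicate block (0.0228, median -0.43), and electron transport without Cyr61 KO replicate 1 (0.00424). The lipid droplet list had a median of 0.20 and a mean of -0.06, and the female-biased list a median of 0.0058 and a mean of -0.0036, so that median and mean differed in sign. In the lists too small to test, Alas2 was at 0.24 and Cela1 at -0.58, and neither passed.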

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

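The tests of gene overlap and of shared calls given here were chosen after the result was seen. Counts on the strand opposite to the annotated genes were not used in the comparison. On that strand edgeR called 33 genes, of which 19 were higher in the Cyr61 KO libraries than in the controls. Of the 33 genes, 8 overlap a called gene on the other strand, such as Hcn3 beside Pklr and Gtpbp6 beside Plcxd1. A further measured fact is that 5 of the 33, Cyp2e1, Lpl, Basp1, Cmah and Bahcc1, were also called in the same direction on the annotated strand. These 5 need not be separate from the main comparison either. The source of the opposite-strand counts was not tested, so the 33 calls do not show a separate antisense signal.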

How the results depend on the processing

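Unweighted voom and the settings that combine another test with leaving out control replicate 2 were chosen after the data were seen. The 467 called genes kept their direction wherever a setting gave them a value, but their number did not hold. DESeq2 called 2249 genes, voom with quality weights 4483, no low-count filter 944, library totals 50, the test against a 1.5-fold minimum 66, and DESeq2 without control replicate 2 1501. Leaving out 1 library gave 7 to 878 genes. In the simulation DESeq2 made a mean of 34 false calls against 5.4 for edgeR, and voom called 411 genes without the quality weights, so the weights gave the 4483. The cause of the other differences was not tested. Cyr61 ranged from -3.19 to -2.73 with 1 library left out, and missed the threshold only without Cyr61 KO replicate 1. Of 37 lists, 29 passed with the preset correlation, 0 with an estimated one, 3 with fry (lipogenesis, interferon-stimulated and hypoxia genes, the last not among the 29), and 0 and 0 with these 2 tests without control replicate 2; leaving out 1 library gave 26 to 28. The replicate block called 633 genes, 399 of them shared with the main result, and 29 lists, with YAP/TEAD targets gained and endothelial markers lost. The deviations of same-numbered libraries correlated at -0.06, -0.24 and -0.45, which gave no sign that the numbers pair the libraries. With 3 libraries per group this cannot exclude a pairing.

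Medians of 2 lists that had passed changed sign, endothelial markers without control replicate 1, control replicate 3 or Cyr61 KO replicate 3 and with library totals, and hepatocyte markers without control replicate 2 (-0.016). Rela was at 0.0091 with DESeq2, 0.0057 without the filter and -0.16 to 0.12 with 1 library left out. Cyp2a4 was at -0.34 with quality weights, -0.18 with the replicate block and -1.61 to 2.52 with 1 library left out. The lipid droplet list changed its test direction at medians of 0.20 with fry, 0.083 with the CPM filter, 0.078 without control replicate 2, also with an estimated correlation or fry, and 0.14 without Cyr61 KO replicate 3; its medians with 1 library left out ran from 0.056 to 0.26. With 1 library left out, medians ran from -0.30 to 0.53 for clock genes, -0.13 to 0.15 for the unfolded protein response and -0.58 to 0.036 for electron transport. The cause was not tested. In the simulation, at the depth and spread of these libraries, edgeR recovered 12.4% of genes changed 2-fold; depth was not varied.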

Other observations

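The tests of explanations in this part and the gene lists they use were chosen after the results were seen. Several of the genes called higher, among them Cyp2c37, Cyp2c54, Cyp2e1 and Cyp1a2, are genes of hepatocytes around the central vein. In a further list of 20 pericentral genes, 18 had a positive log2 fold change, and edgeR called 3 higher, Ces1d at 1.67, Rnf43 at 1.17 and Cldn2 at 1.11, named after their values were seen. The median was 0.98 against 0.10 for 20 periportal genes, a difference of 0.88 (camera adjusted p = 8.4e-07 for the pericentral list, and adjusted p = 0.196 with an estimated correlation). A higher pericentral programme in the knockouts is a hypothesis that may be worth following.

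Control replicate 2 stood apart from the other controls. A share of large bile duct or gut tissue in the piece sampled may contribute. In that library 16 mucous epithelium genes had a median log2 difference of 2.57 from the other 2 controls, with 13 of 16 higher. Of the 7 mucous epithelium genes that passed the expression filter, 5 were higher, at a median of 1.41, while Tff3 and Cldn3 were lower. Of 11 smooth muscle genes 11 were higher, at a median of 1.19. More nuclear or unspliced RNA may also contribute, since 19 of 21 RNAs listed as nuclear-retained were higher at a median of 0.87. That list also holds protein-coding genes, such as Clk1, Ddx5 and Srsf5, so the count alone does not show more nuclear RNA. Whether poly(A) selection was weaker stayed open, with 25 of 36 histone genes higher at a median of 0.65, short of the difference of 1 set for it, but 4 of the 10 that passed the expression filter higher at a median of -0.29.

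Matrix and immune lists were lower together in the knockouts, and so were ribosomal protein genes, listed as a measure of RNA quality. The ribosomal median was -0.76 with 28 of 28 negative. The ribosomal list mean was highest in control replicate 2, at 8.73 log2 CPM against 7.36 to 8.39 in the other libraries. That library had the smallest share of reads counted in genes, 50.9%. Among the other libraries, Cyr61 KO replicates 2 and 3 had the lowest ribosomal means, 7.58 and 7.36 log2 CPM. They also had the smallest remaining shares of reads in genes, 82.8% and 84.6%. Whether the list followed read assignment therefore stayed open. Control replicate 2 alone did not account for 6 of the lower lists, the matrix, macrophage, SYK, NF-kB, neutrophil and dendritic cell lists. Without it the median nearest to 0 among the 6 was -1.02. Outside the 6, the medians of B and plasma cell and stellate cell markers were then -0.58 and -0.34, and that of PDGF genes was -0.72. The endothelial list mean minus the macrophage list mean differed by 2.40 between the groups on the log2 scale, with no overlap. This difference argued against an equal loss of all non-hepatocyte cells. It follows from the list changes given above, so it is no separate support. It does not address a smaller share of some of these cell types, which stayed open. Of the 10 splits of the 6 libraries 1, the real one, gave as many called genes, 467 against at most 0 in the others by edgeR, although in those up to 1180 genes had an unadjusted p under 0.05 and DESeq2 called up to 33; 10 splits are too few for a share under 0.05. The genotype stays open as a biological explanation and was not tested further.

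Lipogenic genes were higher and immediate early genes lower. More feeding before collection stayed open. Fasting-induced genes had a median of 1.05 with 9 of 13 positive, past the level set as evidence against more feeding. They went both ways, however, with an SD of 1.72 (camera adjusted p = 0.00878, adjusted p = 0.322 with an estimated correlation, and 0.0674 without control replicate 2). Collection at another time of day could not be told apart from the genotype. In phase with Bmal1, 5 of 5 clock genes had a positive log2 fold change, with 1 called. Their median was 1.17 (camera adjusted p = 3.5e-04, and adjusted p = 0.196 with an estimated correlation). Of 8 genes of the opposite phase 3 were positive and 5 negative, with 0 called, at a median of -0.30 (camera adjusted p = 0.290). Per1, called lower above, is not among these 8. The medians had opposite signs and differed by 1.47, more than the 1 set for this explanation. However, the opposite-phase genes varied between knockouts. Their median log2 differences from the rest of the group were -0.17, 1.63 and -1.13 in Cyr61 KO replicates 1, 2 and 3. The difference between the medians therefore does not separate time of day from genotype.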
